A study of Pimephales promelas with 16 samples.

How the data were processed

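The data were 16 2-colour Agilent arrays of fathead minnow brain, with 3 arrays for each of 5 groups and 1 array for the solvent. Per the labels' protocols, each Cy5 sample was a pool of total RNA from 3 animals, DNase-treated, and 900 ng per array was labelled with Agilent's 2-colour Quick-AMP kit. The Cy3 channel of every array held a common reference, and no dyes were swapped, so every ratio is sample over reference. Per the file headers, the arrays were scanned and read with Agilent Feature Extraction 10.1.1.1, which gave mean spot intensity and median local background intensity for each dye. Feature Extraction also gave processed intensities, after background subtraction, surrogate values near background and linear and LOWESS dye normalization, and their log10 ratio, per the file headers. The deposited value table holds log2 ratios of Cy5 over Cy3 for 15234 rows, of which 26 are control features. Its scale and direction were found by setting each column against the log ratios of the same array. For 15 columns the correlation was 0.952 to 0.996 and the slope 0.910 to 0.994, so the values are on a log2 scale in the direction Cy5 over Cy3. The centring step that made them stays unknown.

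The column medians of the deposited table were -0.07, 0.13 and 0.01 for fluoxetine 1 to 3, 0.01, -0.13 and 0.04 for venlafaxine 1 to 3, and -0.14, -0.01 and 0.17 for carbamazepine 1 to 3. They were -0.14, 0.03 and 0.01 for mixture 1 to 3, 0.12, 0.03 and 0.08 for control 1 to 3, and -0.03 for the alcohol array. The column of control 3 did not follow its scanner file in the deposited row order, so the deposited values were also used with that column taken in probe-name order.

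Analysis was run in R 4.3.3 with limma 3.58.1 and the package data.table (version 1.17.8). Mean intensities were background-corrected with normexp and an offset of 50, and normalized within each array by loess with control features at weight 0. Control features (536 of 15744) were then left out, and 97 spots on 89 probes that the scanner software marked as outliers were set to missing. Log2 ratios were fitted with limma's lmFit and empirical Bayes moderation as 6 group means over all 16 arrays, with 10 residual and 3.45 prior degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method over 15208 probes, with a threshold of 0.05 (15196 probes for the alcohol array). Every adjusted p in the text is limma's unless another test is named. The fit was tested on simulated data with each probe's spread from the real arrays and 250 changed probes per size and comparison over 5 simulations. Between 4.03% and 7.58% of calls were false, depending on the comparison. Values were drawn independently for each probe and array, with no effect of slide or signal shared between probes. The shares of false and of recovered calls from simulated data therefore hold for such arrays only, and may not hold for the real ones.

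The comparisons were each exposure against controls, any difference among exposures and controls, the mean of the 4 exposures against controls, each pair of exposures, the mixture against the sum of the 3 single drugs, and alcohol against controls. These, their tests and most alternatives were fixed before the data were examined. Added after the data were seen were the deposited values with control 3 re-ordered, the sample-channel signal as a covariate, the probes above background on all arrays, the fit without carbamazepine 1 and carbamazepine 2, and the slide 3 arrays alone. The alternatives fixed in advance covered background correction, normalization, the sample channel alone, the deposited table, a filter on dim probes, outlier spots, slide and replicate number as blocks, array weights, the arrays in the fit, an ordinary model and an adjusted p of 0.10. Slides and scan days were read from the file headers as batches, and slide as a fixed block was used beside the within-slide values, since slides held several groups. Replicate numbers were not taken to pair the arrays, as described with the dependence on the processing. Class medians were compared by exact 2-sided permutation of array labels, with 30 such tests in the family. Simulations of unchanged groups used 20 draws.

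The probe names in the files carry no gene names: 0 of 15208 probes had a gene name, systematic name or description of their own, and 0 matched an entry among the 64593 genes of the gene table for the assembly fPimPro1.hap1.1. The 31 gene lists fixed in advance were therefore not tested. The rule for named genes, fixed in advance, took per comparison with control the 12 largest rises and 12 largest falls among named genes past the threshold whose 3 exposed arrays lay beyond all 3 controls, well above background on every array of both groups. Without gene names it was reduced, after the data were seen, to the 2 largest rises and 2 largest falls for carbamazepine against controls. These were taken among probes with no spot left out on any array and are given by probe identifier and sequence. No per-sample column of the deposited table went unused. Median Cy5 signal above background was 25.3 to 71.9 scanner units per array, which limits how well low levels can be compared.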

Results

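Gene expression was measured in the brain of the fathead minnow (Pimephales promelas), a small freshwater fish used widely in ecotoxicology, after exposure to human pharmaceuticals. Fish received fluoxetine (an antidepressant that blocks serotonin reuptake), venlafaxine (an antidepressant that blocks serotonin and noradrenaline reuptake), carbamazepine (an anticonvulsant that blocks voltage-gated sodium channels) or a mixture of all 3, or were left untreated as controls. Each of these 5 groups had 3 arrays, and a solvent group given alcohol only had 1 array, for 16 arrays in all. Every array carried a Cy5-labelled pool of brain RNA from 3 animals of mixed sex beside a Cy3-labelled common reference pooled from untreated liver, brain and gonad. The study description calls the arrays of a group biological replicates, and the labels give no dose or exposure time. The array held 15208 probes of 60 bases, each spotted at 1 position, and the files pair none of them with a gene name, so results are given for probes and for classes of probes.

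The sample channel was weak and uneven. The median Cy5 signal above background ranged from 25.3 to 71.9 scanner units per array, against 226 to 332 for Cy3. Between 29.1% and 74.3% of probes were well above background in Cy5, and between 70.2% and 92.3% in Cy3. The median Cy5 signal averaged 59.9 ± 12.5 in controls, 42.9 ± 8.56 in the fluoxetine group, 39.1 ± 9.07 in the venlafaxine group, 37.7 ± 9.17 in the carbamazepine group and 37.7 ± 15.1 in the mixture group (SD, n = 3 each). No spot of a probe was saturated. The number of arrays limits the precision of every comparison, and the median 95% confidence interval of a drug-to-control difference was ± 0.53 on the log2 scale.

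**Figure D1:**
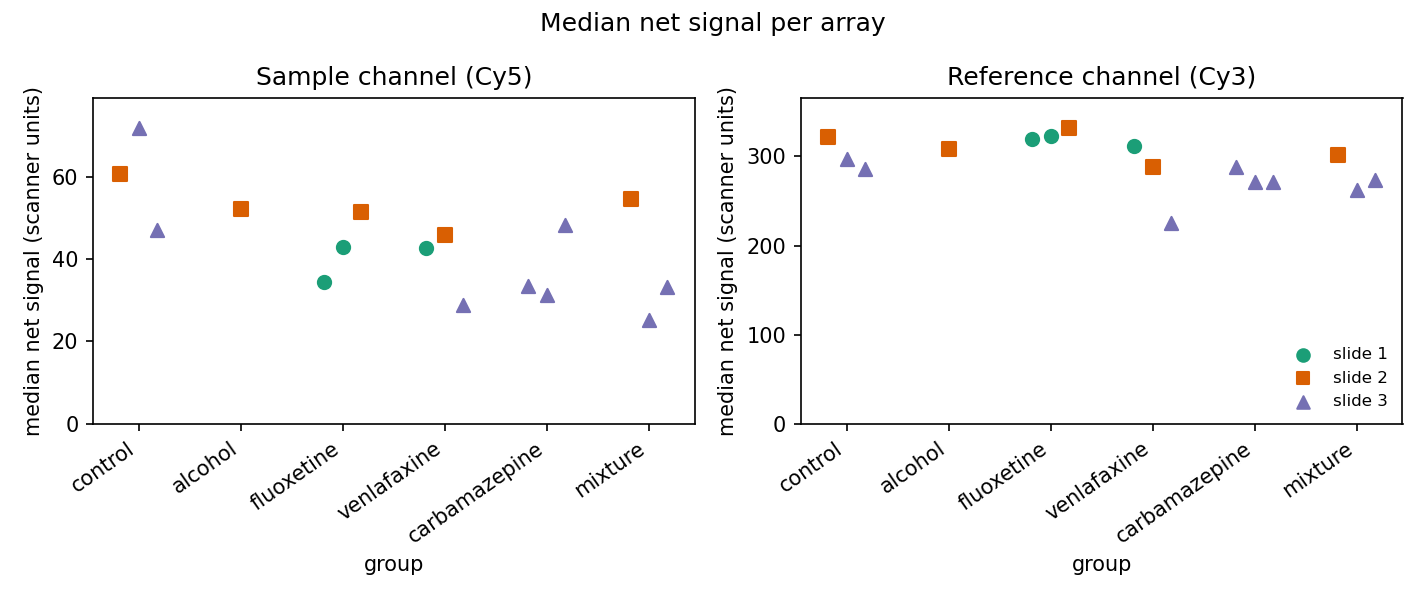
Median signal above local background of each array, in scanner units, for the sample channel (Cy5, left) and the reference channel (Cy3, right), by group; each point is 1 array and its shape and colour give the slide. Cy5 lay between 25.3 and 71.9 and Cy3 between 226 and 332.

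The arrays came from 3 slides scanned on 2 days. Slide 1 held fluoxetine 1, fluoxetine 2 and venlafaxine 3. Slide 2 held control 3, the alcohol array, fluoxetine 3, venlafaxine 1 and mixture 3, and slide 3 held control 1, control 2, the 3 carbamazepine arrays, mixture 1, mixture 2 and venlafaxine 2. The leading principal component of the log2 ratios took 48.4% of the variance and the next 11.8%. No pair among the 120 pairs of arrays had identical signals.

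Brain RNA differed from the mixed-tissue reference at many probes in every group. On all 16 arrays, 159 probes were at least 2-fold and 46 at least 4-fold above the reference, while 52 were at least 2-fold and 1 at least 4-fold below it. By the mean over arrays, 1343 probes (8.83%) lay at least 2-fold above the reference and 500 (3.29%) at least 2-fold below. In Cy5, 2054 probes were well above background on all arrays and 1535 on none. All samples carried the same dye, so these levels include any dye bias of the probe. Such a bias cancels in the comparisons between groups only as far as it is the same on every array, which was not tested.

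Exposure to carbamazepine against no treatment gave the most altered probes of the 4 exposures. Relative to controls, 105 probes fell and 73 rose with carbamazepine at adjusted p 0.05, which is 1.17% of the 15208 tested. Of these, 107 were well above background on all 6 arrays and had no spot left out on any array of the study. Among them the 60 that fell had a median log2 change of -1.84 and the 47 that rose a median of 1.37. An unadjusted p under 0.05 was reached by 3324 probes, where 760.4 are expected by chance. That number, here and below, is an average, and counts can lie far from it where probes vary together. Fluoxetine against venlafaxine, for example, gave 211.

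The probes that fell were mostly those richer in brain than in the reference. Probe classes were set on the 10 arrays of the other groups, with a mean log2 ratio of at least 1 for brain-enriched and at most -1 for reference-enriched. Of the 105 probes that fell, 85 were brain-enriched, 20 lay between and 0 were reference-enriched. Of the 73 that rose, 3 were brain-enriched, 62 lay between and 8 were reference-enriched. The median log2 ratio of the 1285 brain-enriched probes was 1.01 ± 0.21 with carbamazepine and 1.91 ± 0.05 in controls (SD, n = 3 each). Arrays without carbamazepine also lay below the controls at these probes, with 0.45 on fluoxetine 1, 1.20 on fluoxetine 2 and 1.30 on venlafaxine 2. The median Cy5 signal was 33.5, 31.4 and 48.2 scanner units on the carbamazepine arrays and 71.9, 47.0 and 60.7 on the controls. For the 518 reference-enriched probes the median log2 ratios were -0.80 ± 0.20 and -1.77 ± 0.07 (SD, n = 3 each). Each difference gave an exact 2-sided permutation p of 0.1, the smallest that 3 arrays against 3 allow, and an adjusted p of 0.6 over the 30 class tests. With slide as a block the median changes were -0.62 and 0.82, and with Agilent's processed signals they were -1.13 and -0.12. In those signals the median change of all probes was -0.20. The reference-enriched class thus changed sign there but still lay above the median of all probes. In the main fit both classes lay nearer to the reference with carbamazepine than in controls. The median changes were -0.85 and 1.07 in that fit, and smaller with no normexp offset, at -0.60 and 0.61. The SD of the log2 ratios of all probes was 0.86, 0.75 and 0.93 on carbamazepine 1 to 3 and 1.05, 0.97 and 1.04 on control 1 to 3. It was lowest on fluoxetine 1 (0.52) and highest on the alcohol array (1.18). A fall of the brain-enriched class is thus not told apart here from a narrower spread of all ratios.

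**Figure D2:**
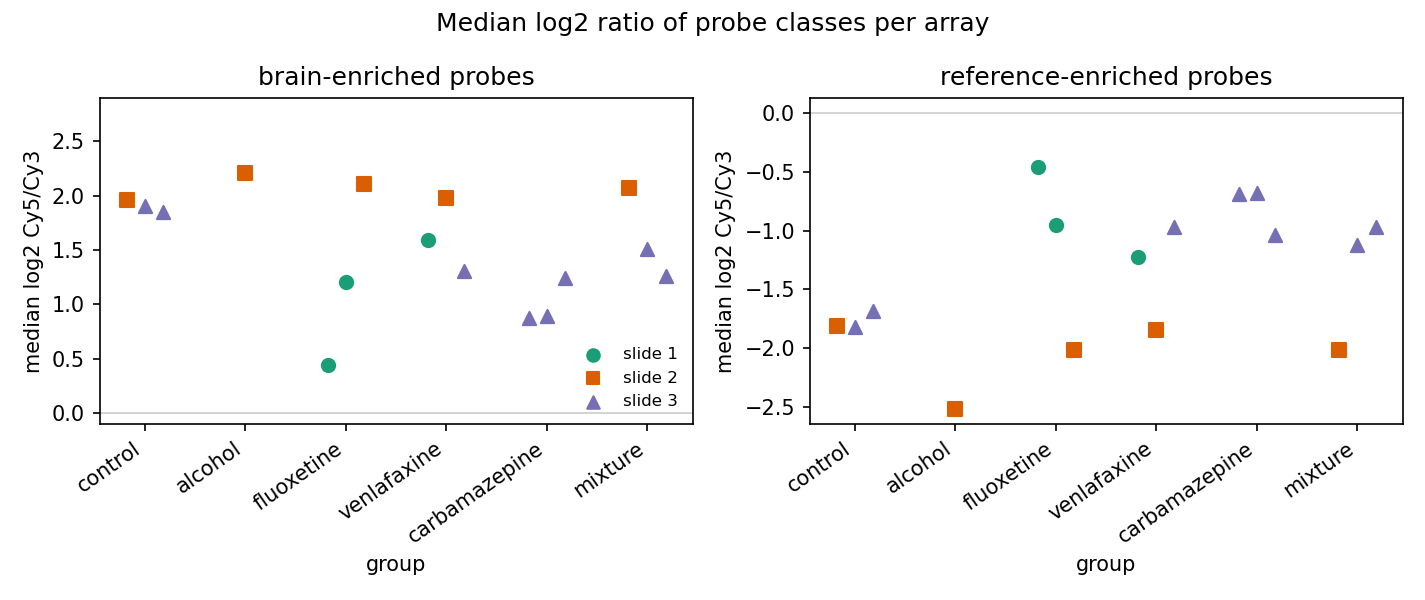
Median log2 Cy5/Cy3 of the 1285 brain-enriched probes (left) and the 518 reference-enriched probes (right) on each array, by group; each point is 1 array and its shape and colour give the slide. The carbamazepine arrays lie between 0.88 and 1.25 on the left, below the controls at 1.85 to 1.96. Arrays of other groups also lie low on the left, with 0.45 and 1.20 on fluoxetine 1 and fluoxetine 2, 1.30 on venlafaxine 2, and 1.51 and 1.26 on mixture 1 and mixture 2.

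The largest fall among probes well above background on all 6 arrays and with no spot left out was at EA_Pp_61270a (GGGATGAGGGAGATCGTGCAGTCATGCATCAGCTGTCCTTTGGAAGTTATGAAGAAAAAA). Its log2 ratio was 1.49 ± 1.07 with carbamazepine and 6.22 ± 0.31 in controls (SD, n = 3 each), a difference of -4.73 (SE 0.79, 95% interval -6.43 to -3.03), or 26.5-fold, with a limma adjusted p of 0.0182. The ratio was 0.48, 1.39 and 2.61 on the carbamazepine arrays and 5.96, 6.56 and 6.14 on the controls. Against controls, this probe differed by -1.51 with fluoxetine (adjusted p = 0.482), -0.55 with venlafaxine (adjusted p = 0.893) and -1.16 with the mixture (adjusted p = 0.752). Within slide 3 the carbamazepine difference was -4.77, and with slide as a block it was -4.35 (adjusted p = 0.0120). It was -3.04 with median centring and -3.13 with scaling between arrays, neither past the threshold.

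The next largest fall was at EA_Pp_56849a (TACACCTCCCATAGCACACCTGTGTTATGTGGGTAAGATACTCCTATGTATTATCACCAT). Its log2 ratio was 1.35 ± 0.96 with carbamazepine and 5.18 ± 1.29 in controls (SD, n = 3 each), a difference of -3.83 (SE 0.67, 95% interval -5.27 to -2.38), or 14.2-fold, with a limma adjusted p of 0.0210. It also lay below controls by a log2 difference of -1.92 with fluoxetine (adjusted p = 0.471) and -1.42 with the mixture (adjusted p = 0.721), neither past the threshold. Within slide 3 the carbamazepine difference was -4.54, and with slide as a block it was -4.06 (adjusted p = 0.00848). It was -2.55 with scaling between arrays and -4.43 with median centring, neither past the threshold.

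The largest rise was at EA_Pp_55207a (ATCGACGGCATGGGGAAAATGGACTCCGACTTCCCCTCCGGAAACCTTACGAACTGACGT). Its log2 ratio was 3.35 ± 1.48 with carbamazepine and 0.70 ± 0.15 in controls (SD, n = 3 each), a difference of 2.65 (SE 0.50, 95% interval 1.57 to 3.73), or 6.28-fold, with a limma adjusted p of 0.0311. The SE, interval and p take 1 spread for all groups, and this probe varied most with carbamazepine. Its SD was 0.24 with fluoxetine and 0.16 with venlafaxine, so the interval may be too narrow for this difference. Mixture arrays averaged 1.15 ± 0.33 (SD, n = 3), a difference from controls of 0.45 (adjusted p = 0.807). Within slide 3 the carbamazepine difference was 2.65, and with slide as a block it was 2.61 (adjusted p = 0.0254). The size depended on the processing, at 1.27 with median centring (not past the threshold) and 4.49 with no normexp offset. The ratio was 1.77 on carbamazepine 3, against 4.69 and 3.60 on the other arrays of that group, which had weaker Cy5 signals.

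The next largest rise was at EA_Pp_70764a (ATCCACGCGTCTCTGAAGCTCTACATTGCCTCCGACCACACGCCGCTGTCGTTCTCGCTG). Its log2 ratio was 2.64 ± 0.37 with carbamazepine and 0.53 ± 0.61 in controls (SD, n = 3 each), a difference of 2.12 (SE 0.47, 95% interval 1.11 to 3.12), or 4.33-fold, with a limma adjusted p of 0.0466. On slide 3 this probe read 1.90 and 1.82 on the mixture arrays and 0.83 and 0.92 on the controls, while on slide 2 it read -0.04 on mixture 3 and -0.18 on control 3. Within slide 3 the carbamazepine difference was 1.76, and with slide as a block it was 1.67 (adjusted p = 0.00848). The size depended on the processing, at 0.96 with median centring and 4.07 with no normexp offset, neither past the threshold.

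**Figure D3:**
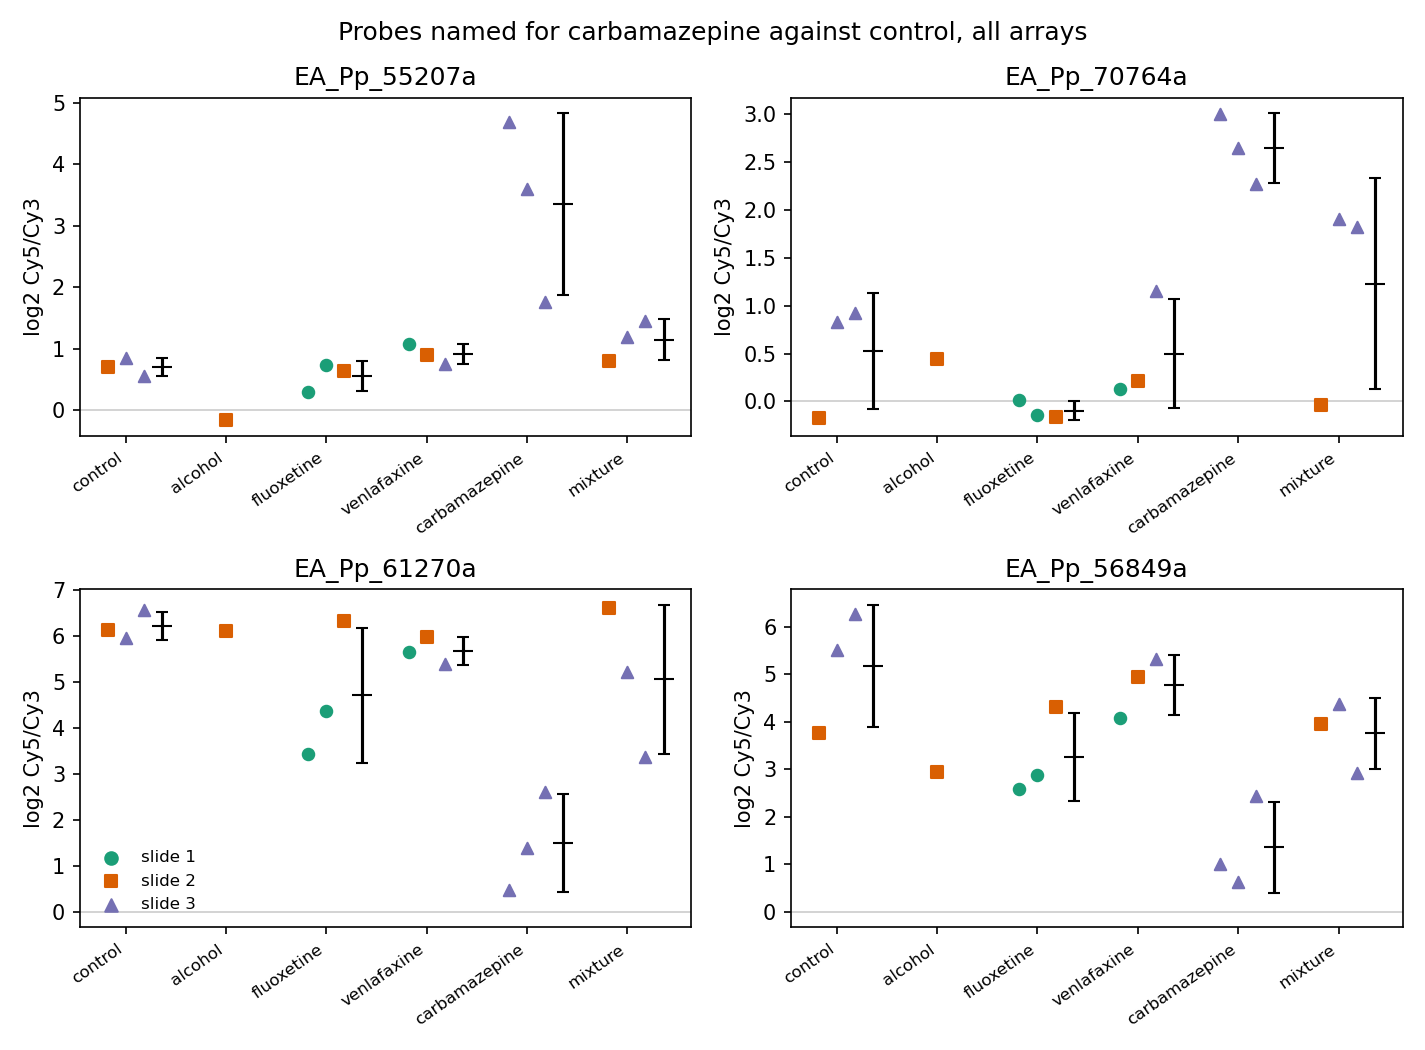
Log2 Cy5/Cy3 of the 4 probes named for carbamazepine on each array, by group; each point is 1 array, its shape and colour give the slide, and bars show the mean and SD of the 3 arrays of a group. The carbamazepine arrays lie above all controls at EA_Pp_55207a and EA_Pp_70764a and below all controls at EA_Pp_61270a and EA_Pp_56849a.

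The carbamazepine test compared 3 arrays on slide 3 with 2 controls on slide 3 and 1 on slide 2. With slide as a block 505 probes passed (247 fell, 258 rose), 177 of the 178 among them with the same sign, and within slide 3 alone, a choice made after the data were seen, 1676 passed (824 fell, 852 rose). With Agilent's processed signals 578 passed (505 fell, 73 rose), where the median log2 change of all probes was -0.20. Scaling between arrays left 1 and median centring in place of loess left 0. The Cy5 signal of each array as a covariate, a choice made after the data were seen, left 7. The count was 7, 3 or 13 without control 1, control 2 or control 3, and 6, 7 or 356 without carbamazepine 1, carbamazepine 2 or carbamazepine 3. Of the 105 probes that fell, 5 were well above background on no carbamazepine array, and of the 73 that rose, 10 were so on no control array, so their fold is not given.

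Fluoxetine against no treatment gave no probe past the threshold in limma. The lowest adjusted p was 0.273, and 1600 probes (10.5%) had an unadjusted p under 0.05, where 760.4 would come from chance alone. The ordinary unmoderated model also gave 0, as did the fit with slide as a block. The brain-enriched class of 1339 probes had a median log2 ratio of 1.16 ± 0.77 with fluoxetine and 1.87 ± 0.05 in controls (SD, n = 3 each; exact 2-sided permutation p = 0.4). On the brain-enriched probes set for carbamazepine, the medians were 0.45 and 1.20 on fluoxetine 1 and fluoxetine 2 of slide 1, 2.11 on fluoxetine 3 of slide 2, and 1.85 to 1.96 on controls. In simulated data, a log2 change of 1 was called at 40% of changed probes for this comparison and a change of 2 at 89.2%.

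Venlafaxine against no treatment gave no probe past the threshold in limma. The lowest adjusted p was 0.867, and 785 probes (5.16%) had an unadjusted p under 0.05, close to the 760.4 that chance gives. The ordinary model and the fit with slide as a block each gave 0, and with the block 1013 probes had an unadjusted p under 0.05. The 1224 brain-enriched probes had a median log2 ratio of 1.65 ± 0.28 with venlafaxine and 1.95 ± 0.05 in controls (SD, n = 3 each; exact 2-sided permutation p = 0.2). In simulated data, a log2 change of 1 was called at 39.2% of changed probes for this comparison and a change of 2 at 93.6%.

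The mixture of the 3 drugs against no treatment gave no probe past the threshold in limma. The lowest adjusted p was 0.721, and 1031 probes (6.78%) had an unadjusted p under 0.05, where 760.4 would come from chance alone. The ordinary model and the fit with slide as a block each gave 0, as did the slide 3 arrays alone (2 against 2, chosen after the data were seen). The number with an unadjusted p under 0.05 was larger in these fits, at 1576 with the block and 3137 on the slide 3 arrays. The 1205 brain-enriched probes had a median log2 ratio of 1.70 ± 0.32 with the mixture and 1.96 ± 0.05 in controls (SD, n = 3 each; exact 2-sided permutation p = 0.4). At the 105 probes that fell with carbamazepine, the median log2 difference from the slide 3 controls was -0.49 on mixture 1 and -0.96 on mixture 2. Venlafaxine 2 of the same slide, without carbamazepine, differed by -0.40, and fluoxetine 1 and fluoxetine 2 of slide 1 by -1.001 and -0.63 from the mean of all controls. On slide 2, mixture 3 differed from control 3 by a median of 0.02 at those probes. In simulated data, a log2 change of 1 was called at 40% of changed probes for this comparison and a change of 2 at 93.6%.

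A test for any difference among the 4 exposures and the controls passed at 32 probes. With slide as a block it passed at 3, and without any 1 control, carbamazepine 1 or carbamazepine 2 at 0. The count was 219 without mixture 3, 106 without fluoxetine 3, 15, 13 and 8 without fluoxetine 1, venlafaxine 1 and mixture 1, and 5, 3 and 2 without fluoxetine 2, venlafaxine 3 and venlafaxine 2. The mean of the 4 exposures against controls gave 0 probes in limma and 0 in the ordinary model, with 2181 (14.3%) at an unadjusted p under 0.05. With array weights 1493 passed (470 fell, 1023 rose). In simulated data, that contrast called 68.4% of probes changed by 1 on the log2 scale and 96.8% of those changed by 2.

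Direct comparison of the drugs gave probes past the threshold between carbamazepine and each of fluoxetine and venlafaxine. All carbamazepine arrays were on slide 3, which held no fluoxetine array and 1 venlafaxine array. These counts therefore include any difference between slides. Between fluoxetine and carbamazepine 269 probes differed, 218 lower and 51 higher with fluoxetine. Between venlafaxine and carbamazepine 128 differed, 60 lower and 68 higher with venlafaxine. Of the 51 probes higher with fluoxetine, 38 were among the 105 that fell with carbamazepine against controls, where independent lists would share 0.352. Of the 68 higher with venlafaxine, 60 were among those 105, where independent lists would share 0.469. In the other direction, 35 of the 218 and 26 of the 60 were among the 73 that rose with carbamazepine, against 1.05 and 0.288 for independent lists. Both comparisons of each pair use the same carbamazepine arrays, which the values for independent lists leave out, so the overlaps are not independent evidence.

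Slide as a block left fewer calls between these drugs, with every probe keeping its sign. No slide held both fluoxetine and carbamazepine arrays, and with the block 0 probes passed, while 1248 of the 15208 tested had an unadjusted p under 0.05. The 218 probes lower with fluoxetine went from a median of -1.81 (SE 0.35) to -1.08 (SE 0.37) and the 51 higher from 1.37 (SE 0.24) to 1.16 (SE 0.32). Of the 218, 116 were well above background on all fluoxetine arrays and 15 on none. Between venlafaxine and carbamazepine 8 passed with the block (2 lower, 6 higher with venlafaxine). The 60 lower with venlafaxine went from -1.52 (SE 0.27) to -1.15 (SE 0.27) and the 68 higher from 1.71 (SE 0.29) to 1.52 (SE 0.30), with 8 residual degrees of freedom in place of 10. Of the 60, 39 were well above background on all venlafaxine arrays and 4 on none. The medians of the lower probes thus include probes near the floor. With Agilent's processed signals the split turned to 208 lower and 388 higher with fluoxetine, and to 64 lower and 320 higher with venlafaxine. In those signals the median log2 change of all probes against controls was -0.20 for carbamazepine, -0.04 for fluoxetine and -0.12 for venlafaxine. A part of the turned splits from that offset was not tested. Scaling between arrays left 21 probes for fluoxetine (13 lower, 8 higher) and 3 for venlafaxine (2 lower, 1 higher), and median centring left 0 for both. The fluoxetine count was 54, 8, 51 and 95 without fluoxetine 1, fluoxetine 2, carbamazepine 1 and carbamazepine 2, and the venlafaxine count 25, 71, 0, 14 and 21 without venlafaxine 1, venlafaxine 2, venlafaxine 3, carbamazepine 1 and carbamazepine 2.

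The mixture differed from carbamazepine alone at 8 probes, 7 higher and 1 lower with the mixture, and at 12 with slide as a block. The 7 that were higher had all fallen with carbamazepine against controls, and both comparisons use the same carbamazepine arrays. Scaling between arrays, median centring and the ordinary model each left 0 probes, and with Agilent's processed signals 122 passed (3 lower, 119 higher). Without carbamazepine 1, carbamazepine 2, mixture 1 or mixture 3 the count was 0, without carbamazepine 3 it was 56 and without mixture 2 it was 21.

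Mixture against fluoxetine, mixture against venlafaxine and fluoxetine against venlafaxine each gave 0 probes in limma, 0 in the ordinary model and 0 with slide as a block. An unadjusted p under 0.05 was reached by 483, 332 and 211 probes in that order, fewer than the 760.4 that chance gives. In simulated data, a log2 change of 2 was called at 92%, 94% and 92% of changed probes in these comparisons.

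Additivity was tested as the mixture effect minus the sum of the 3 single-drug effects. No probe passed in limma or in the ordinary model, 1 passed with slide as a block, 4 with array weights, and 1849 (12.2%) had an unadjusted p under 0.05. The median 95% interval was ± 1.06 on the log2 scale, and in simulated data a departure of 1 was called at 3.6%, a departure of 2 at 31.6% and a departure of 3 at 70.8% of changed probes.

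The alcohol array stood above the controls at 120 probes and below them at 3. These 123 probes rest on a single array whose own spread was taken from the other groups. All 120 were well above background on the alcohol array, 35 were so on all 3 controls and 28 on none, so their fold is not given. Among the 1936 probes well above background on all arrays in both channels, a choice made after the data were seen, 0 passed. With slide as a block 92 passed, and 70 of the 123 were among them. With normexp and no offset 0 passed, with Agilent's processed signals 1, and without control 1, control 2 or control 3 the count was 21, 55 or 70.

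**Figure D4:**
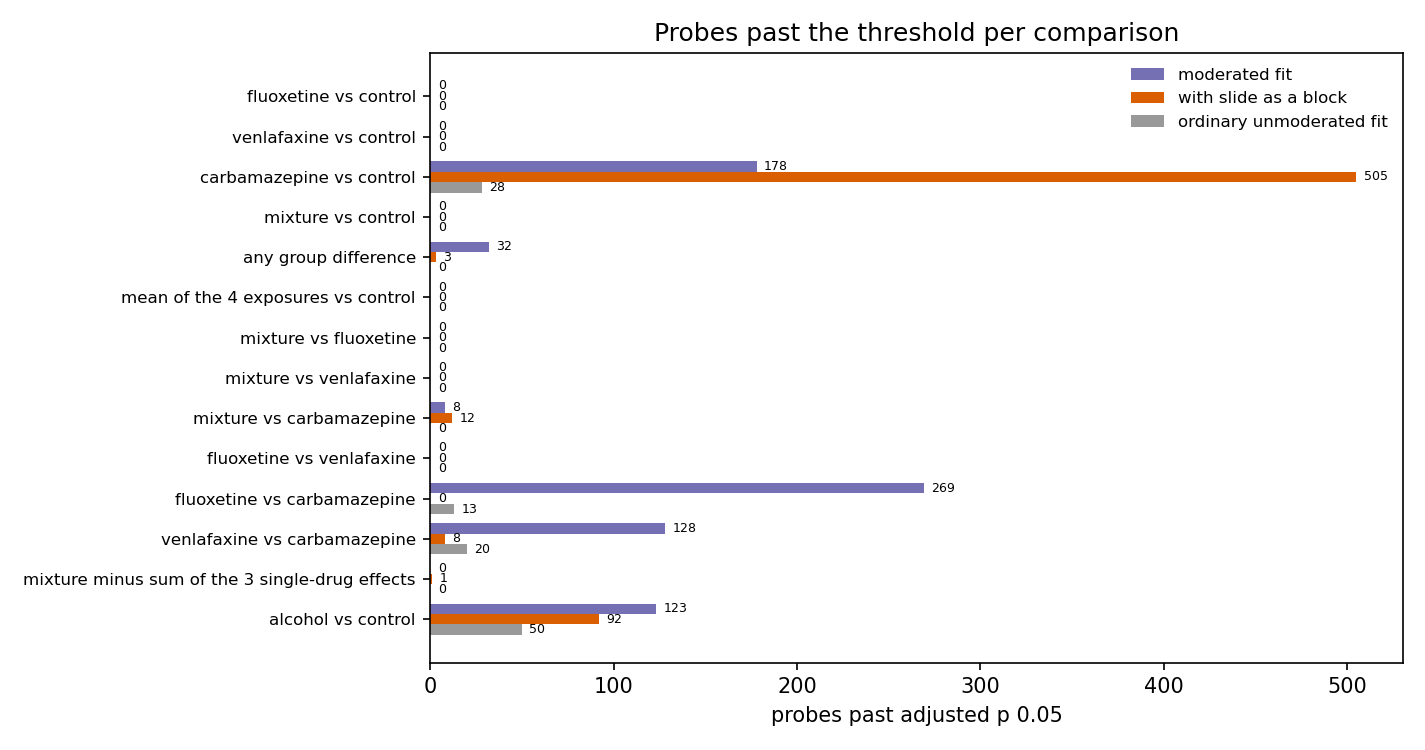
Number of probes past adjusted p 0.05 in each comparison, for the moderated limma fit over all arrays, the same fit with slide as a block and the ordinary unmoderated fit. Carbamazepine against control gave 178, 505 and 28, and fluoxetine, venlafaxine and the mixture against control gave 0 in each.

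Changes against the shared controls were correlated across the 15208 probes, which are not independent replicates. Pearson's r was 0.82 for fluoxetine with venlafaxine, 0.52 for fluoxetine with carbamazepine, 0.69 for fluoxetine with the mixture, 0.55 for venlafaxine with carbamazepine, 0.72 for venlafaxine with the mixture and 0.68 for carbamazepine with the mixture. Unchanged simulated groups set against the same controls gave 0.50 for every pair. Covariances exceeded the simulated covariance of 0.0498 by 0.0673, 0.0982, 0.0549, 0.0702, 0.0329 and 0.107 in the same order. The 3 controls cannot be split into parts of at least 2 arrays, so part of the excess may come from them. Every exposure group also had a weaker mean Cy5 signal (37.7 to 42.9 scanner units) than the controls (59.9). A part of the excess from that shared difference was not tested. Scaling between arrays lowered fluoxetine with carbamazepine to 0.11 and fluoxetine with venlafaxine to 0.61.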

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

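The tests of sample-channel signal, of slides and of the reference channel for the carbamazepine probes, and the test of slide 2 for the alcohol array, were chosen after the results were seen. The test of single arrays and the splits of the samples were set before.

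Carbamazepine drew a closer look because it differed from another exposure in a direct test: 269 probes against fluoxetine, 128 against venlafaxine and 8 against the mixture. With slide as a block these counts were 0, 8 and 12, all probes kept their sign, and the median changes went from -1.81 and 1.37 to -1.08 and 1.16 for fluoxetine, from -1.52 and 1.71 to -1.15 and 1.52 for venlafaxine and from -1.25 and 1.75 to -1.13 and 1.69 for the mixture.

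The 178 probes past the threshold with carbamazepine came with weak Cy5 signal on 2 of its 3 arrays. Weak signal as the whole cause was tested by choosing 178 probes without each carbamazepine array in turn: the left-out array shifted by a median of 1.42, 1.19 and 0.80, against at most 0.70, 0.74 and 0.55 on mixture 1, mixture 2 and venlafaxine 2 of the same slide, whose Cy5 signals were 25.3, 33.2 and 28.8 against 33.5, 31.4 and 48.2. The smallest gap was 0.246, with an SD of 0.113 among those 3 arrays, the outcome set for weak signal not being the whole cause. Fluoxetine 1 of slide 1 (Cy5 34.3) shifted by 0.57, 0.39 and 0.49 from the mean of all controls. On the same measure the left-out arrays shifted by 1.56, 1.23 and 0.83. However, the probes were ranked with a spread pooled over all groups, to which these comparison arrays belonged. Probes at which they departed from their own group ranked lower, and the left-out array had no such limit. The gap therefore cannot decide whether weak signal was the whole cause. A difference between slides as the whole cause is argued against, since 177 probes passed with the same sign with slide as a block. The reference channel is argued against too, since the Cy3 shift in the direction of the call was -0.0215 against a ratio change of 1.55. Weak signal, as the whole cause or a part, and handling within slide 3 stay open. Fluoxetine 1 lay at -1.001 at the 105 fallen probes and read 0.45 at the brain-enriched class, below the carbamazepine arrays (0.88 to 1.25). With Cy5 signal as a covariate 7 probes passed. The median fall went from -1.84 (SE 0.33) to -1.48 (SE 0.37) and the median rise from 1.28 (SE 0.25) to 0.97 (SE 0.26). Each was a smaller change with a larger error. A response to carbamazepine stays open as a hypothesis beside these.

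The 123 probes of the alcohol array rest on 1 array. Among the 12 exposed arrays set alone against the controls, 1 gave as many probes (carbamazepine 1, 424) and the other 11 gave 0 to 17. By the rule set before, 1 such array is the outcome that variation of a single array would give. That array is from the group with 178 probes of its own, a limit that the rule did not hold. Variation of a single array therefore stays open. Slide 2 as the whole cause is argued against, since 70 of the 123 passed with the same sign with slide as a block. A part played by slide 2 stays open, and differences from control 3, which is on slide 2 itself, cannot test it. At the 120 higher probes mixture 3, fluoxetine 3 and venlafaxine 1 lay above control 3 by medians of 0.40, 0.47 and 0.26. The exposed arrays of slide 3 differed from the controls of that slide by -0.02 (carbamazepine 3) to 0.35 (mixture 1). Of these probes 28 were well above background on no control. An effect of the solvent stays open and untested, with no second array.

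Of the splits of the 6 arrays of each pair of groups there are 10, too few for a share under 0.05. For carbamazepine against control the real split gave 178 probes and the highest other 0, and 1 of the 10 splits gave as many. Fluoxetine against carbamazepine gave 269 and 0, venlafaxine against carbamazepine 128 and 0, and mixture against carbamazepine 8 and 0, again with 1 of 10 splits each. Fluoxetine, venlafaxine and the mixture against control, and fluoxetine against venlafaxine, gave 0 and 0, with 10 of 10 splits each. Mixture against fluoxetine gave 0 and 7, and mixture against venlafaxine 0 and 102, with 10 of 10 each; the split with 102 set venlafaxine 1, venlafaxine 3 and mixture 3 against the slide 3 arrays, and the real groups gave 0 with slide as a block.

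For the test of any difference, 6 of 100 splits, the real one included, gave as many probes as the real 32, the highest 2766, so chance cannot be excluded. The split with 2766 kept control 1 with control 2 and carbamazepine 1 with carbamazepine 2, and a split with 1439 kept the 3 carbamazepine arrays together, so their calls hold part of the real grouping. A split with 1269 set mixture 1, mixture 2 and venlafaxine 2, all of slide 3, in place of the controls, and with slide as a block the real groups gave 3. For the mean of the 4 exposures and for additivity, 100 of 100 gave at least the real 0, the highest 1502 and 2431. The 1502 came from the split that kept the carbamazepine arrays together, and the 2431 from a split with mixture 3, fluoxetine 3 and control 2 in place of the controls. Splits with so many calls point to a structure of the samples, of which the real groups are a part in some and not in others.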

How the results depend on the processing

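The table with control 3 in probe-name order, the sample-channel covariate, the probes above background on all arrays, the fit without carbamazepine 1 and carbamazepine 2 and the slide 3 arrays alone were chosen after the data were seen; the other alternatives were set before. The 4 named probes kept their direction under every alternative, though in several they no longer passed the threshold, and their size moved: EA_Pp_55207a from 1.27 with median centring to 4.81 with the deposited table re-ordered, EA_Pp_70764a from 0.96 with median centring to 4.54 with the deposited table re-ordered, EA_Pp_61270a from -2.98 with the deposited table re-ordered to -4.84 with array weights and EA_Pp_56849a from -2.55 with scale to -4.54 on the slide 3 arrays, in fits that kept the 3 carbamazepine arrays, left out no single array and did not use the deposited row order of control 3. Fluoxetine, venlafaxine and the mixture against control stayed at 0 probes, except for 1 with fluoxetine under a replicate block. Cy5 signal above background of 25.3 to 71.9 scanner units limits the comparison of dim probes. The 31 gene lists and their alternatives were not run, as the probes have no gene names. In the deposited table as it stands, control 3 holds values in another row order (correlation 0.985 once re-ordered), so each probe there carries the control 3 value of another probe, and the counts with control 3 re-ordered stand beside those as deposited. For the other counts that differ from the main one, the cause was not tested.

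The carbamazepine against control count of 178 was 323 with no background subtraction, 84 (75 fell, 9 rose) with normexp and no offset, 578 (505 fell, 73 rose) with Agilent processed signals, 1 with scale between arrays, 0 with median centring, 4 with the deposited value table (115, 107 of them falls, with control 3 re-ordered), 505 with slide block, 2287 (860 fell, 1427 rose) with array weights, 2144 with only the groups compared, 857 with the alcohol array as a 4th control, 28 with the ordinary model and 660 at adjusted p 0.10. It was 7 with the sample-channel covariate, 396 on probes above background on all arrays, 0 without carbamazepine 1 and carbamazepine 2, and 1676 on the slide 3 arrays.

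The fluoxetine against carbamazepine count of 269 was 167 with no background subtraction, 603 (324 fell, 279 rose) with no offset, 596 (208 fell, 388 rose) with processed signals, 21 with scale, 0 with median centring and slide block, 0 with the deposited table (218, with 77 lower and 141 higher, with control 3 re-ordered), 649 with array weights, 13 with the ordinary model, 564 at adjusted p 0.10 and 0 without carbamazepine 1 and carbamazepine 2. The venlafaxine against carbamazepine count of 128 was 78 with no background subtraction, 384 (64 fell, 320 rose) with processed signals, 3 with scale, 0 with median centring, 0 with the deposited table (173, with 21 lower and 152 higher, with control 3 re-ordered), 8 with slide block, 517 with array weights, 224 with only the groups compared, 20 with the ordinary model, 360 both at adjusted p 0.10 and with the covariate, 0 without carbamazepine 1 and carbamazepine 2 and 1 on slide 3, which holds 1 venlafaxine array assumed to vary like the other groups.

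The mixture against carbamazepine count of 8 was 49 with no offset, 122 with processed signals, 5 on the sample channel only, 46 with array weights, 53 with the deposited table re-ordered and 29 with the covariate. It was 0 with scale, median centring, the deposited table, only the groups compared, the ordinary model, without carbamazepine 1 and carbamazepine 2, and on slide 3. The count for any difference, 32, was 20 with no background subtraction, 16 with no offset, 96 with processed signals, 3 with slide block, 750 with array weights, 90 at adjusted p 0.10 and 82 on probes above background on all arrays. It was 0 with scale, median centring, the deposited table (28 with control 3 re-ordered), the ordinary model and without carbamazepine 1 and carbamazepine 2.

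The alcohol count of 123 was 576 with no background subtraction, 1 with processed signals, 14 with scale, 6 with median centring, 70 on the sample channel only, 354 with array weights, 50 with the ordinary model, 308 at adjusted p 0.10 and 296 with the covariate. It was 0 with no offset, the deposited table (re-ordered or not) and probes above background on all arrays. The mean of the 4 exposures, 0, gave 1493 with array weights, 1 with the deposited table re-ordered and 1 with the covariate, and additivity, 0, gave 1 with slide block, 4 with array weights and 1 with the covariate.

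With a replicate block the counts were 1 for fluoxetine against control, 518 for carbamazepine against control, 451 for fluoxetine and 288 for venlafaxine against carbamazepine, 5 for mixture against carbamazepine and 88 for any difference. The numbers were not taken to pair the arrays, since 15 of 30 same-numbered pairs correlated above 0.1 and 7 of 15 arrays correlated best with an array of their own number. The median correlation was 0.11 for the same number and -0.07 for other numbers, so a weak link by number is not excluded.

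With 1 array left out, counts ranged from 3 (without control 2) to 356 (without carbamazepine 3) for carbamazepine against control, from 8 (without fluoxetine 2) to 236 (without carbamazepine 3) for fluoxetine against carbamazepine and from 0 (without venlafaxine 3) to 176 (without carbamazepine 3) for venlafaxine against carbamazepine. They ranged from 0 (without mixture 3) to 56 (without carbamazepine 3) for mixture against carbamazepine, from 0 (without control 3) to 219 (without mixture 3) for any difference, from 0 to 1 for additivity (1 without venlafaxine 1 or carbamazepine 3) and from 21 (without control 1) to 70 (without control 3) for alcohol, and stayed at 0 for all other comparisons.

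The correlation of fluoxetine with venlafaxine, 0.82, was 0.59 with processed signals, 0.61 with scale, 0.45 with median centring and 0.61 with the deposited table re-ordered. Fluoxetine with carbamazepine, 0.52, was 0.11 with scale and 0.19 with median centring, and fluoxetine with the mixture, 0.69, was 0.38 with processed signals, 0.32 with median centring and 0.42 with the deposited table re-ordered. With processed signals the median log2 change of all probes was -0.20 for carbamazepine, -0.19 for the mixture and -0.12 for venlafaxine, and with median centring it was -0.10 for fluoxetine.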

Other observations

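The test of row order was chosen after the result was seen. The deposited column of control 3 had a correlation of -0.0044 with the log ratios of its scanner file in the deposited row order, where the other 15 columns had 0.952 to 0.996. Taken in probe-name order, the column of control 3 correlated at 0.985, as rows written in another order would give. With that column re-ordered, the deposited values gave 115 probes for carbamazepine against control, and 4 as deposited.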
